A study of Arabidopsis thaliana with 6 samples.

How the data were processed

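The data were 6 microarrays, 2 for each of 3 groups of dark-grown Arabidopsis seedlings: air, anoxia, and anoxia with 90 mM sucrose, each treatment lasting 6 h. Groups and experiment numbers (1 and 2) come from the sample titles. Per the labels, each array carried RNA pooled from 4 seedling cultures after extraction, the arrays of a group came from independent experiments, and targets were made by the usual Affymetrix procedure. The deposited values are intensity values on a linear scale, 1 per probe set, for 22810 probe sets. The software behind them, its background correction and its scaling are not given in the sources used here. Their 2% trimmed means were 134 and 83.7 in air, 145 and 87 under anoxia and 78.2 and 140 with sucrose (experiments 1 and 2), so the highest exceeded the lowest by 85.5% and the arrays do not share a common scale. The number of arrays limits the precision.

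From these values, 64 control probe sets were left out, 16 was added to each value, log2 was taken and each array was centred on its median. That centring had been fixed for the case that trimmed means differ by over 10%, so median centring, listed as an alternative before the data were seen, is what is reported. Probe sets with a mean at or above the 30th percentile of the 22746 others were tested, 15922 in all. The test was limma (version 3.58.1, R 4.3.3): lmFit with 1 coefficient per group over all 6 arrays, contrasts, and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over the probe sets of each comparison and a threshold of 0.05. Residual degrees of freedom were 3, and the prior added 6.97. Gene lists were tested with limma's camera at a preset correlation of 0.01, 1 probe set per gene (the brightest), for lists with at least 3 tested genes, adjusted over the 9 such lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way without reference to other genes, were run beside it. Comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

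Experiment numbers recur in every group, and the titles call them experiments, so they were treated as pairing the arrays, though no shared day is stated. Checked across probe sets, the difference between replicates correlated at r = 0.383 between air and anoxia, 0.392 between air and anoxia with sucrose, and 0.562 between the anoxia groups. The test without the experiment as a block was fixed as the main one. Counts with it (2 residual degrees of freedom, prior 17) stand beside the results they change, as do the changes within each experiment.

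Gene names come from the platform annotation given for these probe sets, matched by gene number to RefSeq's gene table of assembly TAIR10.1, which was used for names only. Of the probe sets without controls, 13513 had 1 gene, 503 several and 8730 none, and 13436 of the first were matched to a locus. Of those tested, 8731 had 1 gene. Several tested probe sets stood for 1 gene in 89 cases, none of them a named gene. The 21 fixed lists held 364 genes, of which 81 have a matched probe set, and a 22nd list, of cytosolic ribosomal proteins, was not run because the tables give no descriptions to build it from. ADH1, PDC1, SUS1, SUS4, HB1, ASN1, DIN1 and HSP101, 8 genes that were to be given in any case, have no matched probe set and are not analysed here. The same holds for the lists of trehalose phosphate, nitrogen assimilation, vascular and seed reserve genes, and the 2 flavonoid genes with a matched probe set were removed by the filter on low values. Markers of organs and cell types were therefore covered by AUR1, EXPA18 and FMA alone.

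Genes were named by rule: in each comparison the 10 with the largest rise and the 10 with the largest fall among probe sets with 1 gene that passed and did not overlap between groups (5 and 5 for anoxia with sucrose against air), up to 4 passing members of each list, and, where fewer than 5 passed, the 5 with the smallest p in each direction. Exceptions are list members that did not pass and are given as examples, and probe sets without a single gene: these were chosen after their values were seen.

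The steps were tested on simulated data for anoxia against air, with 200 of 15922 probe sets changed. With the measured experiment effect and no block, 0% of 2-fold, 10% of 4-fold, 66% of 8-fold and 96% of 16-fold changes were recovered, with 0 false among 86 calls. With the block it was 28%, 92%, 100% and 100%, with 8 false among 168. Without an experiment effect, 6%, 72%, 96% and 100% were recovered without the block, with 18 false among 155. Alternatives tried were pseudocounts of 1 and 64, no filter or the 50th percentile, quantile normalization, no intensity trend, only the arrays of the groups compared, the experiment as a block, leaving out each array, a 2-fold minimum, and a threshold of 0.01. Added after seeing the data were simulations of unchanged groups with an experiment effect (SD 0.479 between experiments, from the covariance of replicate differences), no centring, scaling to a common trimmed mean, the block without the sucrose array of experiment 1, and the block with an estimated correlation.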

Results

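Seedlings of Arabidopsis thaliana were compared after 6 h in air, under anoxia, and under anoxia with sucrose. They belonged to the ecotype Columbia glabra, were raised for 4 days in darkness at 23 °C without added sugar, and then received the treatment for 6 h, with sucrose at 90 mM where it was given. Total RNA was read on Affymetrix arrays, on which a set of short oligonucleotides (a probe set) reports each transcript. The 3 groups held 2 arrays each, 1 from experiment 1 and 1 from experiment 2, and each array carried RNA pooled from 4 seedling cultures. Changes are differences of log2(signal + 16) after each array was centred on its median, so that changes of dim genes are understated, and 15922 probe sets were tested. Values of groups are given as mean ± SD (n = 2) relative to the array median.

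The arrays differed in brightness and in signs of RNA quality. Median signal was 46.2 and 30.8 in air, 45.3 and 32 under anoxia, and 21.2 and 50.6 under anoxia with sucrose, for experiments 1 and 2. Signals below 16, where the pseudocount outweighs the signal, made up between 26.1% and 43.6% of an array. Replicate arrays correlated across the tested probe sets at r = 0.905 in air, 0.914 under anoxia and 0.856 under anoxia with sucrose (genes are not independent replicates). On the sucrose array of experiment 1 the 3' probe set of the actin control read 21.6 times the 5' probe set, against 1.70 to 4.24 on the other 5 arrays, and the GAPDH ratio was 7.61, against 1.38 to 2.42. The probe set for 25S ribosomal RNA read 1211 on the anoxia array and 848 on the sucrose array of experiment 1, 168 on the air array of that experiment, and 4.2 to 12.5 in experiment 2.

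**Figure D1:**
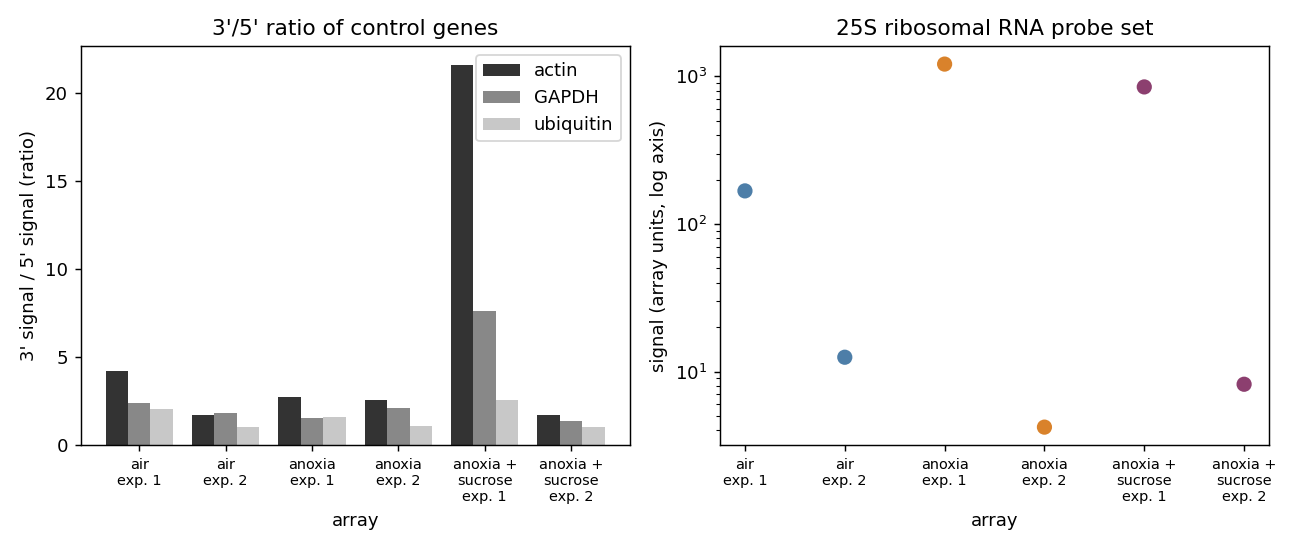
Left, 3'/5' signal ratio of the actin, GAPDH and ubiquitin control probe sets on each of the 6 arrays (bars start at 0); right, signal of the 25S ribosomal RNA probe set on the same arrays, on a log axis in array units. The sucrose array of experiment 1 has the highest ratios of all 3 control genes (21.6 for actin), and the 25S signal is above 100 on the 3 arrays of experiment 1 and at most 12.5 on those of experiment 2.

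The first comparison, anoxia against air without sucrose in either, addressed the response to 6 h without oxygen. Anoxia raised genes that other work has tied to low oxygen. AT5G10040, a gene of unknown function in the core hypoxia list, rose from -1.40 ± 0.29 to 4.42 ± 1.00, a log2 change of 5.82 ± 0.70 (SE, adjusted p = 0.0192). CML38, a calmodulin-like protein, rose by 4.75 ± 0.61 (adjusted p = 0.0206), and AT4G10270, of the wound-responsive protein family, by 4.62 ± 0.71 (adjusted p = 0.0393). AT3G10040, a trihelix transcription factor, rose by 3.60 ± 0.57, and AT3G27220, a kelch repeat protein, by 3.56 ± 0.52. All 5 belong to the core hypoxia list, and 2 named genes outside it rose as well. These were AT2G36690, of the oxoglutarate-dependent oxygenase family, by 2.54 ± 0.40, and AT1G64500, of the glutaredoxin family, which rose 4.29-fold (adjusted p = 0.0393).

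Anoxia lowered 7 named genes. IAA29, a repressor of the auxin response, fell by 2.45 ± 0.39 on the log2 scale (adjusted p = 0.0437), and LBD29, a transcription factor of lateral root formation, fell by 1.90 ± 0.31 (adjusted p = 0.0487). AT4G25780, of the secreted CAP protein family, fell by 3.59 ± 0.46, to -0.59 ± 0.90 under anoxia (adjusted p = 0.0206). AT2G43860, of the pectin lyase family, fell by 2.59 ± 0.35 and AT1G49200, of the RING finger family, by 2.56 ± 0.34. AT5G08350, with a GRAM domain, fell by 2.36 ± 0.34, and AT5G61570, of the protein kinase superfamily, fell at least 4.29-fold (adjusted p = 0.0437). For AT5G10040, AT3G10040, AT2G43860, AT1G49200, AT5G61570 and LBD29 both arrays of the dimmer group read below 16, so their changes are lower bounds. The 14 named genes moved in their direction in both experiments, for example by 6.73 and 4.91 for AT5G10040 and by -2.52 and -2.38 for IAA29. The naming rule, which asks for no overlap between groups, requires that direction, so it is no separate evidence.

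Across the core hypoxia list, 19 of 20 tested genes lay above 0 and the median log2 change was 3.16 (3.495 in experiment 1 and 2.604 in experiment 2). Over all probe sets 5 of the 20 rose and 0 fell by limma, and 12 rose when adjusted over the list alone. With the experiment number as a block the counts over all probe sets were 13 up and 1 down, the latter AT3G61930. The list stood above the other genes in the set test (adjusted p = 1.84e-20), with adjusted p = 0.236 with an estimated correlation. All 7 tested genes of the heat shock list lay above 0, with a median of 2.21 (1.87 and 2.30 by experiment). Over all probe sets 0 of these 7 passed in limma, although 7 did when adjusted over the list alone and 7 with the experiment as a block. Their unadjusted p lay between 0.000225 and 0.0355. Examples are the small heat shock protein genes AT2G29500 at 2.63 ± 0.47 (adjusted p = 0.0651) and ATHSP22.0 at 2.41 ± 0.50 (adjusted p = 0.127). The set test gave adjusted p = 1.57e-14 for this list, and adjusted p = 0.0638 with an estimated correlation.

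The list of sucrose breakdown and glycolysis had 5 tested genes: TPI, GAPC2, PPDK and the pyruvate kinase genes AT5G08570 and AT5G63680. No gene of sucrose breakdown was among them. Their median change was 0.82 (0.88 and 0.65 by experiment). GAPC2, a cytosolic glyceraldehyde phosphate dehydrogenase, was at 0.82 ± 0.42 (adjusted p = 0.933). No single gene of the list passed, but the list did (adjusted p = 0.00236, and adjusted p = 0.236 with an estimated correlation). Expansins and other wall-loosening genes had a median of -0.95 (-0.32 and -1.06 by experiment), with 9 of 9 tested genes below 0. The expansin gene EXPB1, at -1.52 ± 0.35, passed when adjusted over the list alone. Over all probe sets its adjusted p was 0.2, and 0.0056 with the experiment as a block. The list test gave adjusted p = 7.14e-05, and adjusted p = 0.214 with an estimated correlation. The auxin list of 5 genes had a median of -0.44 (-0.20 and -0.91 by experiment, adjusted p = 0.0164, and adjusted p = 0.236 with an estimated correlation). Of its members 1 lay above 0, and IAA29 was the 1 that passed over all probe sets. Without the air array of experiment 2 the auxin list gave adjusted p = 0.241, and without the anoxia array of experiment 2 it gave 0.08.

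Of the other lists with a set test, none passed. Sugar starvation genes had a median of 0.59 (adjusted p = 0.124) and sugar transporters and invertases of -0.11 (adjusted p = 0.867). The median was 0.31 for oxidative stress genes (adjusted p = 0.271) and 0.11 for reference genes (adjusted p = 0.867). The starvation list did pass without the air array of experiment 2 (median 0.80, adjusted p = 0.015). Among the 7 lists with only 1 or 2 tested genes, PDC2, a pyruvate decarboxylase of ethanol fermentation, was at 3.27 ± 0.58 (adjusted p = 0.0638, and 0.00038 with the experiment as a block), while AT4G17260, the lactate dehydrogenase of that list, was at 0.38 ± 0.44. The starch genes APL3 and SBE2.2, the ethylene regulator EIN3, the etiolated and green plastid genes PORB and LHCB4.1, the mitotic kinase AUR1, the root hair expansin EXPA18 and the stomatal regulator FMA lay between -0.86 and 0.41. None of them passed with or without the block.

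**Figure D2:**
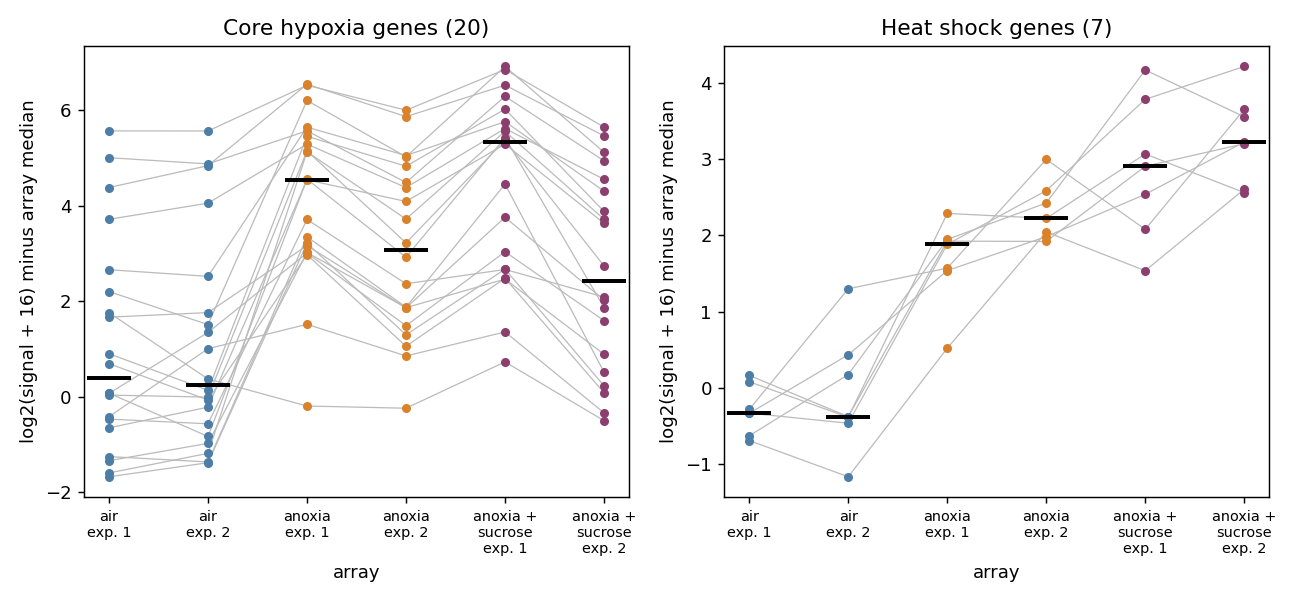
Level of each tested gene of the core hypoxia list (left, 20 genes) and of the heat shock list (right, 7 genes) on the 6 arrays, as log2(signal + 16) minus the array median; grey lines join the values of a gene and black bars are medians over genes. The heat shock genes changed by a median of 2.21 from air to anoxia and were 1.12 higher with sucrose than without it, while the core hypoxia genes with sucrose lay above the anoxia array in experiment 1 (median change 0.33) and below it in experiment 2 (-0.43).

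In all, limma called 37 of 15922 probe sets between anoxia and air, 17 higher and 20 lower. An unadjusted p under 0.05 was seen for 956, where evenly spread p-values would give 796. That number is no safe yardstick, since sucrose against anoxia gave 161 in the same fit. With the experiment number as a block limma called 404, 153 higher and 251 lower, among them all 37, and 1879 had an unadjusted p under 0.05. Each of the 404 had the same direction in both experiments, which selection by the test favours. The changes of experiments 1 and 2 correlated across probe sets at r = 0.381, with 58.5% in the same direction. In all, 431 probe sets changed more than 2-fold the same way in both (172 up and 259 down) against 80 in opposite ways. Any single array mattered: limma called 2 or 4 without an air array (experiment 1 or 2) and 80 or 81 without a sucrose array. It called 0 without either anoxia array (502 or 862 with an unadjusted p under 0.05).

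The second comparison, anoxia with sucrose against anoxia, addressed what 90 mM sucrose does during anoxia. The small heat shock protein genes were higher with sucrose. All 7 tested genes of the heat shock list lay above 0, in both experiments, with a median log2 change of 1.12 (1.00 in experiment 1 and 1.13 in experiment 2). The list stood above the other genes in the set test (adjusted p = 1.58e-11). With an estimated correlation the adjusted p was 0.0871, and 0.166 with the block as well, and fry gave adjusted p = 0.19. AT2G29500 was at 1.76 ± 0.47, from 2.24 ± 0.50 without to 4.00 ± 0.30 with sucrose, and ATHSP22.0 at 1.68 ± 0.50. These 2 passed when adjusted over the list alone (adjusted p = 0.0249 for each), and 4 did so with the experiment as a block. Over all probe sets 0 passed either way in limma, where unadjusted p lay between 0.00371 and 0.443 over the 7 genes. Of the 2 arrays with sucrose, that of experiment 1 had the high 3'/5' ratios, and without it the list's median was 1.37. That fit has no block and sets the sucrose array of experiment 2 against the anoxia arrays of both experiments.

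Genes that are known to rise in darkness or sugar shortage were lower with sucrose as a group. The 6 tested genes all lay below 0, with a median of -0.57 (adjusted p = 0.00209, and adjusted p = 0.42 with an estimated correlation). The median was -0.91 in experiment 1, on the sucrose array with the high 3'/5' ratios, and -0.16 in experiment 2. IVD, isovaleryl-CoA dehydrogenase of leucine breakdown, was at -0.81 ± 0.54 and MCCA, of the same pathway, at -0.60 ± 0.46. Neither passed, and the list gave adjusted p = 0.112 without the anoxia array of experiment 1 and adjusted p = 0.053 without the sucrose array of experiment 1. The oxidative stress list of 4 genes had a median of 0.42 (0.79 and 0.33 by experiment, adjusted p = 0.00989, and adjusted p = 0.42 with an estimated correlation). Its member GSTU25, a glutathione transferase, was at 1.52 ± 0.42 and passed when adjusted over the list alone (adjusted p = 0.0182) but not over all probe sets (adjusted p = 1). The list's p rose to 0.163 without the anoxia array of experiment 2 and to 0.565 without the sucrose array of experiment 1.

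Core hypoxia genes showed no common direction with sucrose: the median was -0.11 (adjusted p = 0.552), 0.33 in experiment 1 and -0.43 in experiment 2. The result depended on single arrays, with a median of -0.85 without the sucrose array of experiment 1 and 0.84 without that of experiment 2. It was 0.36 without the anoxia array of experiment 1 and -0.58 without that of experiment 2. These fits have no block and set the array left in a group against arrays of both experiments. The difference between experiments therefore enters these 4 medians, and they do not measure an effect of sucrose alone. AT5G10040 was at 0.21 ± 0.70, CML38 at 0.14 ± 0.61 and PDC2 at 0.09 ± 0.58. The list of sucrose breakdown and glycolysis, tested on glycolytic genes only, did not pass (median -0.07, adjusted p = 0.454). The lists of sugar transporters (-0.05, adjusted p = 0.765) and wall-loosening genes (0.13, adjusted p = 0.552) did not pass either. Nor did those of auxin response (0.32, adjusted p = 0.0702) and reference genes (0.17, adjusted p = 0.348). Tested genes of the lists too short for a set test lay between -0.63 (PORB) and 0.60 (EXPA18), with adjusted p = 1 for each.

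For single genes, limma called 0 probe sets at an adjusted p under 0.05. An unadjusted p under 0.05 was seen for 161, and the smallest adjusted p was 1. Evenly spread p-values would give 796, so the p-values of this fit run high and 796 is no yardstick for it. Named by the smallest p, with none passing, AR781 was at 1.68 ± 0.36 and GRX480, a glutaredoxin, at 1.66 ± 0.38. AT4G10390 was at 1.36 ± 0.32, AT1G28190 at 1.33 ± 0.31 and AT2G29500, above, at 1.76 ± 0.47. On the lower side AT2G38820 was at -1.35 ± 0.46, AT4G10910 at -1.17 ± 0.37, AT2G36690 at -1.15 ± 0.40, AT5G45310 at -0.97 ± 0.33 and AT1G28080 at -0.85 ± 0.28. With the experiment number as a block 3 probe sets were called, all higher with sucrose, and 558 had an unadjusted p under 0.05. None of the 3 has a single gene in the annotation used here, and the largest change among them was 2.37 ± 0.39 (adjusted p = 0.0444 with the block). Changes in experiments 1 and 2 correlated across probe sets at r = -0.00537, and 46.9% had the same direction. In all, 57 changed more than 2-fold the same way in both (48 up and 9 down) against 12 in opposite ways.

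**Figure D3:**
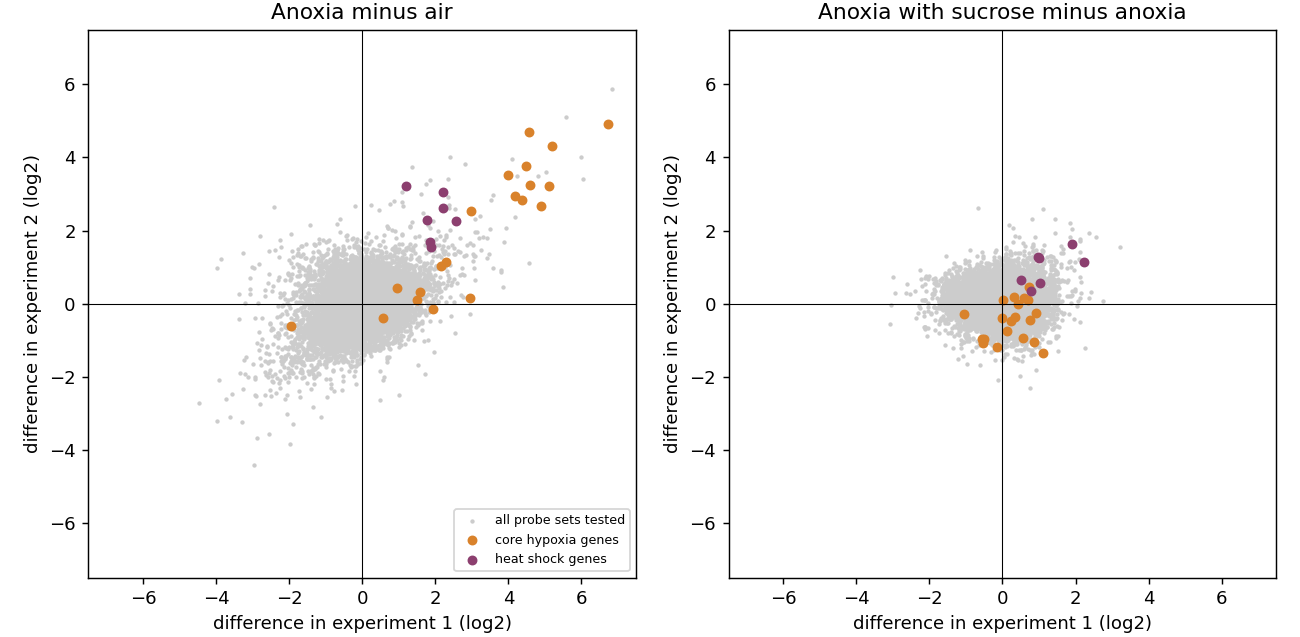
Log2 change in experiment 1 (horizontal) and in experiment 2 (vertical) of the 15922 tested probe sets, for anoxia minus air (left) and anoxia with sucrose minus anoxia (right); orange marks the 20 core hypoxia genes and purple the 7 heat shock genes. Across probe sets the experiments correlated at r = 0.381 on the left and -0.00537 on the right, and all 7 heat shock genes lie above 0 in both experiments in both panels.

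The third comparison, anoxia with sucrose against air, takes both treatments together, so that neither oxygen nor sucrose is tested by itself. Over all probe sets 4 of 20 core hypoxia genes and 4 of 7 heat shock genes rose by limma, and both lists passed the set test, the former with adjusted p = 0.305 with an estimated correlation. AT5G10040 rose by 6.03 ± 0.70 (adjusted p = 0.017), CML38 by 4.897 ± 0.612 (adjusted p = 0.017). AT4G10270 rose by 4.44 ± 0.71 (adjusted p = 0.0467) and AT3G03270, a universal stress protein, by 4.16 ± 0.68 (adjusted p = 0.0486). Of the heat shock list, AT2G29500 rose from -0.40 ± 0.09 in air to 4.00 ± 0.30, by 4.40 ± 0.47 (adjusted p = 0.017), ATHSP22.0 by 4.09 ± 0.50, AT1G53540 by 3.16 ± 0.43 and AT5G37670 by 2.96 ± 0.44. AT1G54050, a small heat shock protein gene outside the fixed list, rose by 4.40 ± 0.59 (adjusted p = 0.0176). Among the genes that fell were AT4G25780 (-3.45 ± 0.46), AT5G08350 (-2.64 ± 0.34), AT1G49200 (-2.60 ± 0.34), AT1G09575, of the mitochondrial calcium uniporter family (-2.24 ± 0.35), and AT2G43860 (-2.18 ± 0.35).

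The heat shock list had a median of 2.998 (2.873 and 3.379 by experiment), with 4 of 7 genes up over all probe sets, 7 when adjusted over the list alone and 7 with the experiment as a block. Its set test gave adjusted p = 8.2e-19, and adjusted p = 0.0421 with an estimated correlation, but 0.0985 with an estimated correlation and the block. Core hypoxia genes had a median of 2.64 (3.12 and 1.70 by experiment), with 4 of 20 up over all probe sets, 12 when adjusted over the list alone and 12 with the block. The set test gave adjusted p = 3.97e-18, and adjusted p = 0.305 with an estimated correlation. Wall-loosening genes had a median of -0.89 (-1.23 and -0.60 by experiment, adjusted p = 0.00253, and adjusted p = 0.305 with an estimated correlation). Of these, EXPA4, EXPB1 and XTH16 passed when adjusted over the list alone and, over all probe sets, with the block. Oxidative stress genes had a median of 0.67 (1.06 and 0.43 by experiment, adjusted p = 0.0113). The sucrose breakdown and glycolysis list, tested on glycolytic genes only, had a median of 0.65 (0.47 and 0.67, adjusted p = 0.0241). With an estimated correlation each of these lists gave adjusted p = 0.333. Without the sucrose array of experiment 1 these last lists gave adjusted p = 0.157 and 0.0674. The glycolysis list also lost its call without the sucrose array of experiment 2 (adjusted p = 0.134) or an air array (0.0555 and 0.0658), and with no centring (0.53, adjusted p = 0.0833). Starvation genes (-0.18, adjusted p = 0.51), transporters (-0.18, adjusted p = 0.655), auxin genes (-0.26, adjusted p = 0.245) and reference genes (0.28, adjusted p = 0.372) did not pass. The auxin list did pass without the air array of experiment 1 (-0.48, adjusted p = 0.0473). PDC2 was at 3.37 ± 0.58 (adjusted p = 0.0585, and 0.000251 with the block).

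In this comparison limma called 40 probe sets, 24 higher and 16 lower, and 1075 had an unadjusted p under 0.05. The block raised the count to 527 (258 higher and 269 lower), among them all 40. The changes of both experiments correlated across probe sets at r = 0.355. In both, 492 probe sets changed more than 2-fold the same way (230 up and 262 down) against 81 in opposite ways. Without the sucrose array of experiment 1 the count was 23, and 66 with the block. Without the sucrose array of experiment 2 it was 71 and without an anoxia array 17 or 21. Without either air array limma called 0 (731 or 1033 with an unadjusted p under 0.05).

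Comparisons that share arrays also share their chance values. Anoxia with and without sucrose, each against the same air arrays, shared 9 called probe sets up and 13 down, 22 in all. Simulated unchanged groups shared 0.09 on average (2 at most in 100 simulations), and independent lists of these sizes would share 0.0256 and 0.0201. Their changes correlated across probe sets at r = 0.808 against 0.5 in the simulations, with a covariance of 0.258 against 0.106. These simulations leave out the experiment effect. With 1 common to the arrays of an experiment, unchanged groups gave a covariance of 0.0643 and shared 0 calls. Both kinds of simulation share the air arrays as the data do. The excess in covariance, 0.153 and 0.194, is therefore over that share, as far as the simulated noise matches that of the arrays. The air arrays, 1 for each comparison if divided, were not divided.

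Whether sucrose moved the anoxia response back could not be answered from called probe sets. With 0 calls between anoxia with and without sucrose, the number called in opposite directions had to be 0 (with the block, 3 at most and 0 observed), so it carries no information. Unchanged sucrose arrays in 100 simulations without an experiment effect gave 0.3 on average and 3 at most. Of the 17 that rose under anoxia, 13 had a negative change with sucrose (median -0.43), and of the 20 that fell, 18 had a positive one (median 0.29). Among those called with the block, it was 86 of 153 that rose (median -0.108) and 183 of 251 that fell (median 0.231). Shared anoxia arrays tilt such values by chance alone. Over all probe sets the covariance of both changes was -0.0361, against -0.105 in simulations without an experiment effect and -0.0644 in simulations with one. The correlation was -0.188, against -0.323 and -0.276. When 1 anoxia array was compared with air and the other with sucrose, it was 0.347 and 0.0808. Unchanged sucrose arrays with an experiment effect gave 0.155 (0.135 to 0.175) and 0.156 (0.13 to 0.18) there. The observed values lie outside these ranges on opposite sides. The simulated arrays therefore do not match the real ones in this respect, and no conclusion is drawn from the difference. Changes of different experiments, which share neither arrays nor that effect, correlated at 0.0577 and -0.00426. The former lay above its simulated range (-0.0278 to 0.0229) and the latter within its own (-0.0207 to 0.0207).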

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

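The tests of explanations given here were all chosen after the results were seen. Their SE over genes treats genes as replicates and does not measure the spread between arrays. Control probe sets outside the comparisons flagged 2 arrays of experiment 1, because they read more than 2 times the highest air array. The 25S ribosomal RNA probe set read 1211.3 on the anoxia array and 848.2 on the sucrose array of experiment 1, which is 7.23 and 5.06 times the highest air array (167.5). On the sucrose array the 3'/5' ratio was 21.57 for actin, 5.09 times the highest air array, and 7.606 for GAPDH, 3.15 times.

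The sucrose array of experiment 1 stands apart from its replicate. Exchange of its label with the anoxia array of experiment 1 would put the heat shock genes lower on the array that carries the sucrose label. Their median there was higher, by 1 on the log2 scale (SE over genes 0.235). That value holds after centring on the array median. Centring raised it, as median signal in experiment 1 was 21.2 with sucrose and 45.3 without. No other scaling was tried for experiment 1 alone, so the value bears on an exchange only as far as the centring holds. Degraded RNA stays open as a candidate explanation: the 3'/5' ratios of 3 of 3 control genes were above those of the other 5 arrays, but such ratios are what singled the array out, so they are no separate test. A biological difference between the experiments was not tested.

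Heat shock genes were higher with sucrose than without it under anoxia. Degraded RNA on the sucrose array of experiment 1 is argued against as the whole cause. In experiment 2, which does not hold that array, the median was 1.13 (SE over genes 0.175), on 1 sucrose array. In the fit without the doubted array it was 1.369 (SE over genes 0.188), and the core hypoxia median moved to -0.847. That fit sets the sucrose array of experiment 2 against anoxia arrays of both experiments, so the difference between experiments enters both values. For scaling, the smallest median over the mean of both experiments was 0.996, with no centring (SE over genes 0.185). That mean cannot decide about scaling within an experiment, because the shifts cancel in it. Median signal with sucrose was below that of anoxia in experiment 1 (21.2 against 45.3) and above it in experiment 2 (50.6 against 32). Centring therefore raised the change in experiment 1 and lowered it in experiment 2. Other scalings were not tried for each experiment alone, so scaling stays open there, above all for experiment 1. Also open is whether sugar supply or the osmotic effect of 90 mM sucrose could be the source. These cannot be told apart with 0 arrays of another osmoticum. The higher level with sucrose is thus a hypothesis about 7 genes. The set test gave adjusted p = 0.0871 with an estimated correlation, and 0.166 with the block as well. By fry the adjusted p was 0.19, and 0.114 with the block.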

How the results depend on the processing

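Tests without centring, with a common trimmed mean, with the block on 5 arrays, and with the block and an estimated correlation were chosen after the data were seen. The cause was not tested where none is named. The numbers of probe sets called depended on most settings, in the order anoxia against air (37) and anoxia with sucrose against air (40): pseudocount 1 gave 2 and 14, pseudocount 64 gave 82 and 99, no filter 88 and 118, quantile normalization 23 and 22, no intensity trend 14 and 20, the 4 arrays of the groups alone 82 and 17, and a threshold of 0.01 gave 1 and 1. The replicate block gave 404 and 527, and on 5 arrays, without the sucrose array of experiment 1, 277 and 66. Scaling to a common trimmed mean gave 24 in the former. Leaving out 1 array gave 0 to 81 and 0 to 71, a group left with 1 array being assumed to vary like the others. The 50th percentile (32 and 52), a 2-fold minimum (37 and 40) and no centring (40 and 56) stayed within 1.5 times. Sucrose against anoxia had 3 calls with the replicate block and 0 under each other setting (limma, 36 to 1012 with an unadjusted p under 0.05), so that the 0 probe sets moved back under each setting carry no information.

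Lists called numbered 5, 3 and 5 in the 3 comparisons. With an estimated correlation they were 0, 0 and 1, by fry 1, 0 and 1, and with the block and an estimated correlation 0, 0 and 0. Leaving out 1 array gave 4 to 5, 2 to 4 and 3 to 5, and no centring left 4 in the third. The replicate block alone changed none of these counts. Core hypoxia genes changed direction with sucrose to 0.835 without the sucrose array of experiment 2, the range over arrays left out being -0.847 to 0.835. Those fits have no block, so the difference between experiments enters them. With no centring all probe sets shifted by -0.135 with sucrose. No named gene reversed under any setting run, which their choice by large change or small p favours. Among named genes, 102 values in the first comparison and 82 in the third lost the threshold. About 26.1% to 43.6% of signals lay below the pseudocount, where folds are understated.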

Other observations

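Gene families were looked at after the data had been seen, and each test in this part was chosen after the results: 36 families, formed by shared symbol and with at least 5 tested genes, were tested with limma's camera. Probe sets of the mitochondrially encoded nad genes, subunits of respiratory complex I, were higher under anoxia than in air. Over 13 probe sets of 6 genes (7 of them for nad1) the median over genes was 0.83, 0.91 in experiment 1 and 0.77 in experiment 2, and all 6 genes lay above 0 in both. The family test on the brightest probe set of each gene gave a median of 0.84 and adjusted p = 0.00465, but adjusted p = 0.829 with an estimated correlation. By limma 0 of the 13 probe sets passed over all probe sets, 2 did with the experiment as a block. With sucrose against without it the median was 0.61 in experiment 1 and -0.18 in experiment 2. The ribosomal protein families rpl and rps, whose symbols are in lower case like nad, also had positive medians under anoxia. These were 0.585 (6 of 7 genes above 0) and 0.539 (7 of 8), but neither passed the family test (adjusted p = 0.391 and 0.086). Whether the rise is particular to the nad genes was not tested.

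Among the other 8 families past the threshold between anoxia and air, wall and growth families had negative medians: EXPA expansins (-0.65, 0 of 7 genes above 0), XTH xyloglucan transferases (-0.62, 1 of 6 above 0) and RALFL peptides (-0.57, 2 of 7 above 0). So did the auxin repressors IAA (-0.42), the transcription factors BZIP (-0.48), and the PRA (-0.44) and TRM (-0.29) families. The 5 genes of the same kind whose symbols are written bZIP had a median of 0.08, with 3 above 0 and adjusted p = 0.746. Several of these falls were small in experiment 1. Medians for experiments 1 and 2 were -0.186 and -1.057 for EXPA and -0.095 and -0.833 for BZIP. They were -0.195 and -0.721 for PRA, -0.248 and -0.648 for IAA, and -0.627 and -0.798 for XTH. RALFL (-0.737 and -0.499) and TRM (-0.641 and -0.295) fell further in experiment 1. EXPA, XTH and IAA overlap lists described in the report. Aldehyde dehydrogenases (ALDH) lay above 0 in 8 of 8 genes, with a median of 0.46 and adjusted p = 0.0317, but 0.0542 with the block. With sucrose against without it, autophagy genes (ATG) had a median of 0.51 with 7 of 8 above 0, and RALFL genes 0.38 with 7 of 7 above 0 (adjusted p = 0.0165 for each). Their medians were larger in experiment 1, whose sucrose array had the high 3'/5' ratios, than in experiment 2: 0.62 and 0.29 for ATG, 1.00 and 0.22 for RALFL. LSM genes, at a median of 0.70, passed only with the block (adjusted p = 0.0546 without it and 0.00722 with it). With an estimated correlation none of these families passed.

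The nad pattern under anoxia stayed under each scaling tried, the smallest median being 0.754 with a common trimmed mean (SE over genes 0.093). That could hardly have come out otherwise: the median of all probe sets lay between 0.016 and 0.083 under these scalings. Carry-over of ribosomal RNA into the target is argued against as the whole cause by experiment 2 alone, without a measure of the spread between arrays. In experiment 2 the 25S probe set read 4.2 under anoxia, 8.2 under anoxia with sucrose and 12.5 in air. All these readings lie below 16, so their order carries no weight, but neither treated array had a raised 25S signal. The nad medians against the 1 air array of that experiment were still 0.766 (SE over genes 0.104) and 0.575 (SE over genes 0.14). This SE treats genes as replicates and does not measure the spread between arrays. With sucrose against without it the medians were 0.609 (SE over genes 0.105) in experiment 1 and -0.18 (SE over genes 0.069) in experiment 2. For the change in experiment 1 (0.911) carry-over stays open, since 25S was higher on both treated arrays there. It is also open, and was not tested, whether the proportion of mitochondrial to nuclear messenger RNA may have changed under anoxia.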
